A study of Homo sapiens with 17 samples.

How the data were processed

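Small RNA was sequenced from 17 libraries of HCT116 cells, an established human colon carcinoma line. Per the labels' protocols, total RNA was extracted with TRIzol, fragments of 17 to 30 nt were cut from a 15% urea gel, and libraries were made with the Illumina TruSeq small RNA kit. The submitters' processing notes name cutadapt 1.14, Bowtie2 without a version, and the human build hg38, also written GRCh38. How reads were assigned to hairpins, how many mismatches were allowed and how libraries were scaled are not given in the sources used here. The authors deposited a table of the parental and dCTT libraries with 294 miRNA hairpins and a table of the 15 rescue libraries with 1282 hairpins.

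In each table the reference library holds whole-number read counts as deposited: the dCTT library in the first table and a mock library in the second. The other deposited columns hold signal, namely read counts multiplied by a scale factor per library. Every value in all 17 libraries was a whole multiple of its library's smallest step (100% of values, tolerance 0.001 of a read). Whole read counts per hairpin were therefore recovered, and their sum is called depth here. It can exceed the number of reads, since hairpins with a shared mature sequence hold nearly the same counts and a read may enter several of them. After the authors' scaling, the summed value of mir-320a, mir-320b-1, mir-320c-1 and mir-320c-2 lay between 0.946 and 1.25 of that of the reference library; in the parental library it was 0.998. Every fold change below is therefore a change relative to a scale on which the sum of these hairpins, though not each of them, is nearly level. The table of the parental and dCTT libraries lists only hairpins with at least 50.7 in the higher library, as read from the values. Values are called scaled reads below, and hairpins carry their miRBase-style names without the species prefix.

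Libraries were grouped by their genotype labels. The columns of the mock group are named as knockout cells and could be matched to the group but not to its replicate numbers, so these libraries are called a, b and c here. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 4.10 to 271 over hairpins), and each was counted as its own sample. The labels do not say what a replicate number marks. Deviations from the group means were correlated in the 5 comparisons between groups with replicate numbers. Every same-number pair correlated over 0.1 only in C352A against WT (r 0.185 to 0.425 in 3 pairs), which does not show what the numbers share. Over all 18 same-number pairs the median r was -0.020, against -0.013 for other pairs. Mock could not be checked. Hairpins that share a mature sequence, such as let-7a-1 to let-7a-3, hold nearly the same reads in these tables, so their separate values are uncertain and they are not independent. The same holds for mir-107, mir-103a-1 and mir-103a-2 (2831, 2870 and 2970 scaled reads in mock library a), whose changes are 1 signal throughout.

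Before the data were examined, the comparisons, tests, lists, alternatives and the rule for named hairpins were fixed. The fixed plan left the test open to the unit, and since most columns are scaled, limma 3.58.1 in R 4.3.3 was used on log2(value + 1), with eBayes and a mean-variance trend, 2-sided. All 15 rescue libraries entered 1 fit with group as its only term. A hairpin was tested if its mean over the 15 libraries was 10 or more, which left 336 hairpins with 277 names. "Rose" and "fell" mark a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low hairpins. Where a group held 3 reads or fewer of a hairpin, a bound against 3 reads over the group or a ratio with its 95% counting interval is given in place of the fitted value. Floors and the intervals of shares and read ratios cover counting error only. The intervals of the parental over dCTT median and of Spearman's rho take hairpins as independent. They cover the spread across hairpins and not that between libraries.

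Fixed lists of miRNA families were tested with camera, with a preset correlation of 0.01 between hairpins and again with an estimated correlation, and adjusted over 117 tests together (13 lists by 9 comparisons). The lists were the let-7, miR-15/16, miR-17-92, miR-29, miR-30, miR-181 and miR-200 families, the miR-183/96/182, miR-192/194/215 and miR-23/27/24 clusters, the miR-320 copies, hairpins textbook-known to bypass Microprocessor (DGCR8-independent list), and miRNAs of other cell types. The miR-34 family, mir-221 with mir-222, and the hairpins within DGCR8 had fewer than 3 tested members and are given by hairpin. Hairpin sequences, positions and host genes came from GENCODE release 29 on GRCh38. Each hairpin was folded with RNAfold of ViennaRNA 2.7.2, and UGU was sought in the largest central loop extended by 2 nt on each side: 76 tested hairpins carried it, 240 did not, and 20 whose name has copies of both kinds were left out of that comparison. No test was possible between the parental and dCTT libraries; the median of each list was placed among 10000 random lists of the same size matched on mean value.

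Named hairpins were the largest rises and falls past the threshold (10 each way in the 4 main comparisons, 5 in the others) among hairpins at or above the median mean value, with no overlap between the 3 libraries of the 2 groups; the 4 highest members of each list; and mir-320a, mir-484, mir-877 and mir-1306 throughout. In the pair of single libraries they were the 10 highest in each library and the 10 largest ratios each way. Reads were simulated for 336 hairpins from the mock means and each library's scale factor, with a dispersion set to 0.03 and not estimated. All of 30 hairpins raised 4-fold in WT were found (100%), as were 60% of 30 set to 0.5 of their level. Of 276 unchanged hairpins 6 were called. The real spread and share of changed hairpins may differ, so these rates need not hold for these libraries.

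Alternatives were pseudocounts of 0.1 and 10, no filter or a mean of 100, 3 other scalings (each library centred on the median of tested hairpins, on the DGCR8-independent list, or set to equal totals), the replicate number as a block, only the 2 groups compared, no variance trend and leaving out each library. Chosen after seeing the data were count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, keeping the authors' factors, 1 hairpin per name, leaving out the mir-371 to mir-373 cluster with mir-202, other definitions of the UGU class and a replicate block over C352A and WT alone. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.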

Results

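DGCR8 is the RNA-binding partner of the nuclease DROSHA in Microprocessor, the complex that cuts primary microRNA transcripts into hairpins. Its messenger RNA is not measured in small RNA libraries, so the edit itself cannot be read from these data. The series covered parental HCT116 cells (1 library), cells in which the CTT domain of DGCR8 was deleted by genome editing (dCTT, 1 library) and rescued dCTT cells. The rescues were a mock rescue, wild-type DGCR8 (WT), DGCR8 with the C352A change, DGCR8 with the P351A change, or P351A with a treatment labelled ALA, which the labels do not spell out (3 libraries each). The series title asks whether Microprocessor needs hemin to recognise the apical loop of primary microRNAs. The read counts of the parental library summed to 5122793 over the listed hairpins, and its total on the authors' scale was 19.5 times that of the dCTT library. Depth, the sum of read counts over hairpins, ran from 146023 to 587214 in mock, 660126 to 1470755 in WT and 199133 to 1023184 in C352A. It was 1666688 to 2175294 in P351A and 1191542 to 1941805 in P351A plus ALA.

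The hairpin mir-320a, which is made at a transcription start without Microprocessor (chromosome 8, 22244962 to 22245043, minus strand, GRCh38), took a share of the summed read counts that followed the groups. Its intervals take that sum as the number of reads, which it can exceed. The share was 0.929% in the parental library (95% Wilson interval 0.921 to 0.938) and 18.0% in the dCTT library (17.8 to 18.2). In the rescue libraries it was 10.8% to 12.4% in mock, 3.48% to 5.70% in WT, 14.3% to 14.5% in C352A, 8.61% to 10.1% in P351A and 5.94% to 7.13% in P351A plus ALA. On the authors' scale its level was nearly the same in the parental library (30547.9) and the dCTT library (30425).

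Deletion of the CTT domain was accompanied by lower values of most hairpins. The median hairpin was 46.5-fold higher in the parental library (log2 ratio 5.54, 95% interval across hairpins 5.36 to 5.61), with 276 hairpins lower and 18 higher in dCTT cells. The most abundant parental hairpins were mir-100 at 264252 scaled reads against 2983 in dCTT cells, mir-21, an oncogenic microRNA, at 256959 against 4876, mir-191 at 169422 against 2993 and mir-222 at 156800 against 3720. The let-7 hairpins, which restrain growth genes in differentiated cells, had a median log2 ratio of 5.70 over 12 members. Among hairpins at or above the median mean of the 2 libraries, the largest ratios were those of mir-375 (7.34, with 8 reads in dCTT cells), mir-99b (6.53) and mir-200c (6.52). Each log2 ratio here compares these 2 libraries only, with no replicate check and no test.

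On the authors' scale, which itself holds the sum of mir-320 hairpins level, a small set of hairpins kept its level in dCTT cells. The 4 listed DGCR8-independent hairpins had a median log2 ratio of -0.10, at the 0.04 percentile of 10000 random lists, and the 4 miR-320 copies 0.00. Among them mir-877, a mirtron spliced from an ABCF1 intron (chromosome 6, 30584332 to 30584417, plus strand), stood at -0.22 and mir-484, made at the start of the NDE1 gene (chromosome 16, 15643294 to 15643372, plus strand), at 0.38. Higher in dCTT cells by more than 2-fold were 3 hairpins, among them mir-7706 at 1235 against 397 (-1.63). The 5 listed hairpins of other cell types stood at the other end (6.04, percentile 99.5), while most families lay within the bulk: let-7 at percentile 29.5, miR-181 at 39.2, miR-200 at 63.7 and the miR-23/27/24 clusters at 86.2. The median of 6.04 is the value of mir-9-1 to mir-9-3, copies with nearly the same reads, beside mir-145 (5.85) and mir-143 (4.29). That percentile therefore rests mainly on mir-9. With each library centred on its median hairpin, the median log2 ratio became 1.13, so the size of the loss rests on a scale that keeps the sum of mir-320 hairpins level. The medians of the DGCR8-independent list and the miR-320 copies then became -4.50 and -4.41, so their kept level rests on that scale too.

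Wild-type DGCR8 raised most microRNAs over mock. Large rises and falls named here and below are those of hairpins at or above the median mean value whose libraries do not overlap. Large rises with WT included let-7i (log2 fold change 3.83 ± 0.28 SE, adjusted p = 1.84e-08), with 70430 ± 29562 scaled reads (SD, n = 3) against 4740.3 ± 957. Similar was mir-10a, which lies among the HOXB genes (chromosome 17, 48579838 to 48579947, minus strand; 3.80 ± 0.24), with 65995 ± 23541 against 4582 ± 715. Other large rises were mir-30a (3.77 ± 0.34; 3729 ± 929 against 269.6 ± 39.9), mir-196b (3.82 ± 0.40), mir-193b (3.51 ± 0.47), the hypoxia-responsive mir-210 (2.91 ± 0.33) and the p53 target mir-34a (2.76 ± 0.46). In all, 187 hairpins rose and 25 fell (15 without mock library c), with a median log2 fold change of 1.13. The 3 WT libraries lay entirely above or below the 3 mock libraries for 224 hairpins, where chance gives 10%.

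The rise with WT ran through most families. All 12 let-7 hairpins rose (median 1.65; 12 also adjusted over the list alone), and camera placed them above other hairpins (adjusted p = 0.0164; adjusted p = 0.889 with an estimated correlation). All 6 miR-30, all 6 miR-181 and all 6 miR-23/27/24 hairpins rose, with medians of 2.72, 1.81 and 2.12. So did 11 of 12 miR-17-92 hairpins (1.78), all 5 of miR-15/16 (1.48), all 4 of mir-192, mir-194 and mir-215 (1.95) and 3 of 4 of miR-29 (1.78), with the same counts adjusted over each list alone. These 8 family medians stayed above 0 under each other scaling, which gives their sign and not their size. Equal totals lowered the median of all hairpins from 1.13 to -0.27, and calls of single members under that scaling are not given here. In the epithelial miR-200 family 3 of 5 rose (1.17) and in mir-183, mir-96 and mir-182 2 of 3 (0.89), but with equal totals these medians were -0.27 and -0.55. Outside these families mir-222 (1.82 ± 0.17; adjusted p = 0.177 with equal totals), mir-221 (2.26 ± 0.30) and mir-34c (3.42 ± 0.68; 2.44 without mock library c) rose.

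Of the 5 tested hairpins that bypass Microprocessor 1 rose and 1 fell (list median 0.14). Camera did not place this list apart from other hairpins (adjusted p = 0.244, and adjusted p = 0.889 with an estimated correlation). The value of mir-320a, which the scale itself holds close to level, was 0.14 ± 0.09 (adjusted p = 0.213). It turned to -0.58 with median centring and -1.31 with equal totals. The mirtron mir-877 fell (-1.38 ± 0.41, adjusted p = 0.00683; 1351 ± 258 against 3561 ± 919 scaled reads), and the mirtron mir-1226 gave 0.16 ± 0.31. The value of mir-484 rose (1.37 ± 0.54, adjusted p = 0.036), a call lost with median centring (0.175), with no filter (0.165) and without mock library a or b or WT replicate 1 (0.0628 to 0.169) and a value that turned to -0.072 with equal totals. Of the 7 miR-320 copies, mir-320c-2 fell (-0.91 ± 0.26), and camera placed the list below other hairpins (adjusted p = 0.0351; adjusted p = 0.541 with an estimated correlation). Other falls included mir-4521 (-2.30 ± 0.48), mir-1275 (-1.65 ± 0.49; -1.02 without WT replicate 1; adjusted p = 0.051 with no filter) and the mir-6724 copies (-1.19 ± 0.35). The 5 tested microRNAs of other cell types had a median of 0.10, which turned to -0.61 with median centring. Counts in this comparison were 141 up and 82 down with median centring (median of all hairpins 0.42), 180 and 21 centred on the DGCR8-independent list (1.08), and 54 and 126 with equal totals (-0.27).

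**Figure D1:**
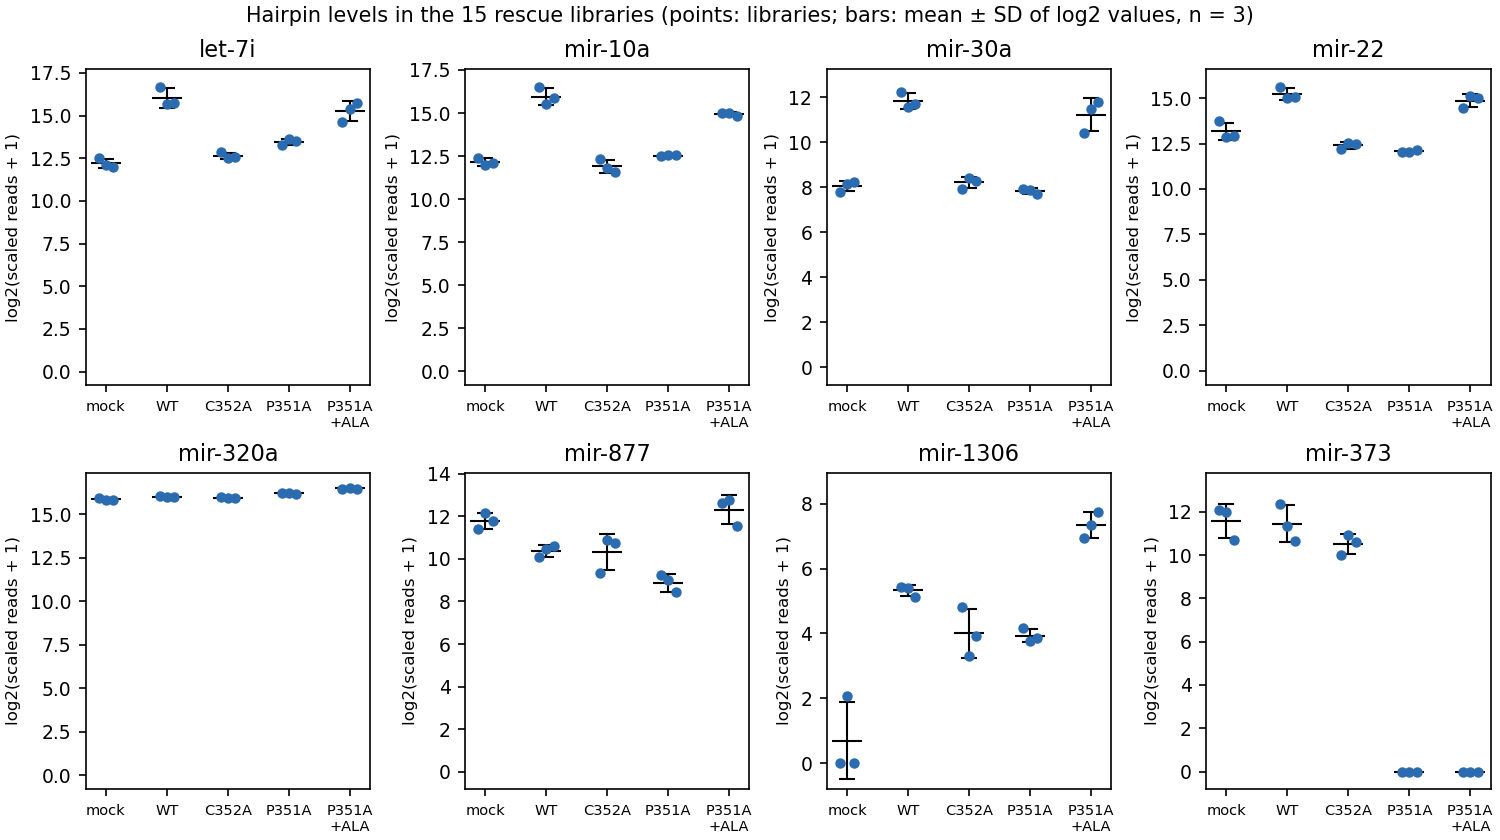
Levels of 8 hairpins in the 15 rescue libraries, as log2(scaled reads + 1) on the vertical axis, with groups along the horizontal axis; points are libraries and bars the mean ± SD of log2 values (n = 3). The let-7i, mir-10a, mir-30a and mir-22 points of WT lie above those of mock and C352A, mir-320a changes by 0.14 from mock to WT (-1.31 with equal totals) and rises by 0.62 from mock to P351A plus ALA (-0.86 with equal totals), and mir-373 is at 0 in P351A and P351A plus ALA.

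**Figure D2:**
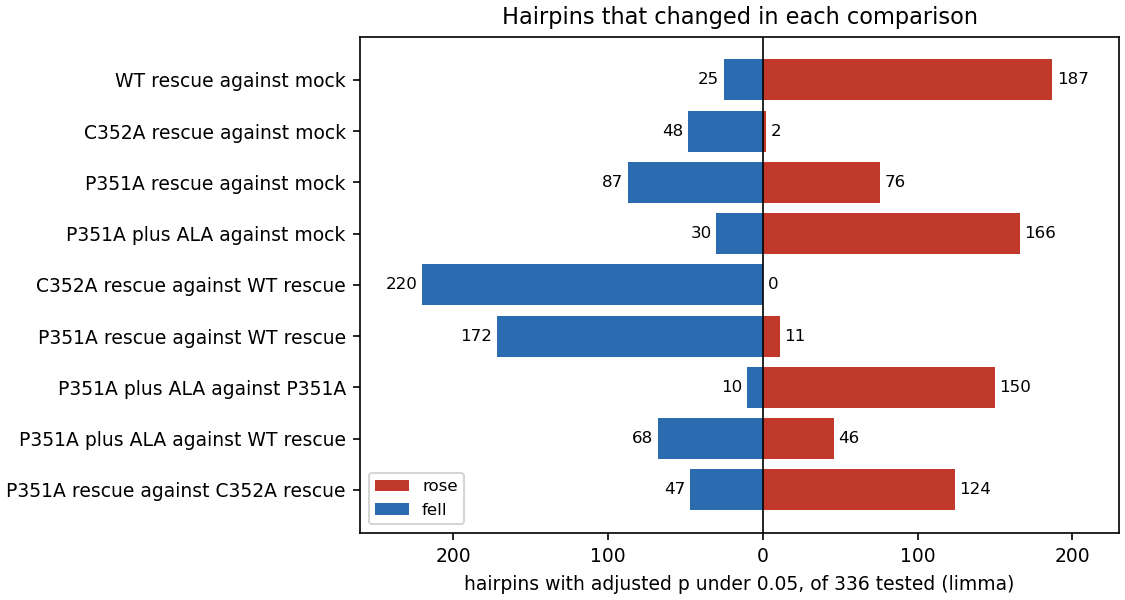
Number of hairpins, of 336 tested, that rose (red, to the right) or fell (blue, to the left) in each comparison at an adjusted p under 0.05 with limma on the authors' scale. WT over mock gave 187 rises and 25 falls and C352A over WT 220 falls; with equal totals the first split turned to 54 and 126.

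Hairpins lost in dCTT cells and hairpins raised by WT were set against each other across 260 hairpins measured in both tables, which share no library. Of the 223 hairpins at least 4-fold lower in dCTT than in parental cells, the median log2 fold change of WT over mock was 1.61; of the other 37 it was -0.37. The loss was above 0 for 242 hairpins and the change with WT for 223. Both were above 0 for 217, among them let-7i, mir-10a and mir-30a, where independent signs would give 208. Across hairpins, which are not independent replicates, Spearman's rho was 0.31 (95% interval 0.192 to 0.425) and Pearson's r 0.561. The rank correlation was 0.453 with a pseudocount of 10.

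**Figure D3:**
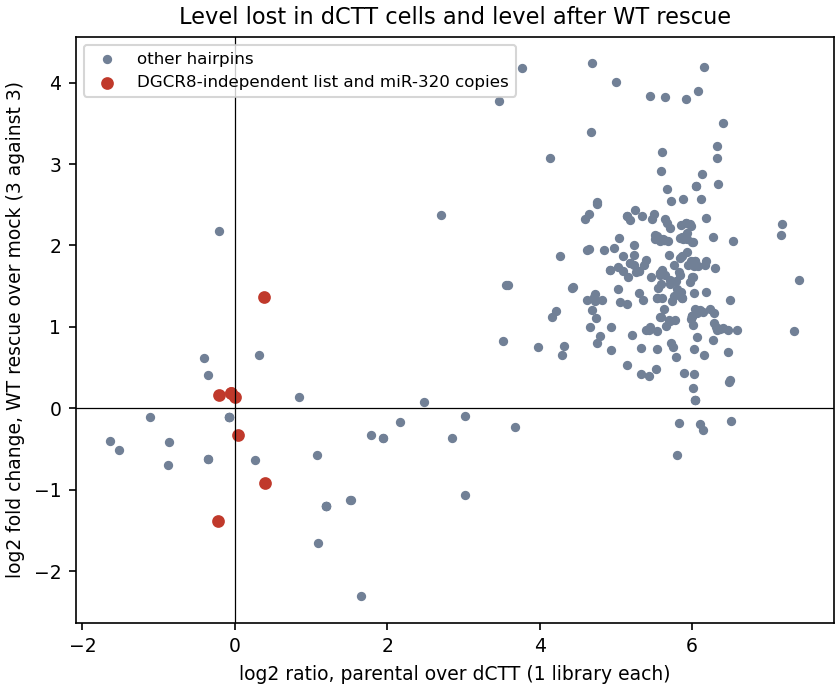
Each point is 1 of 260 hairpins, with the log2 ratio of the parental over the dCTT library (1 library each) on the horizontal axis and the log2 fold change of WT over mock (3 libraries each) on the vertical axis; red points are hairpins of the DGCR8-independent list and the miR-320 copies. Most points lie at the upper right (217 have both values above 0), and the red points lie near 0 on the horizontal axis.

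The C352A form left the microRNAs that WT raised at a low level. Compared with WT, large falls included mir-10a (-4.04 ± 0.24, adjusted p = 8.83e-10; 3934 ± 1091 against 65995 ± 23541 scaled reads), mir-34a (-3.83 ± 0.46), mir-193b (-3.64 ± 0.47), mir-30a (-3.62 ± 0.34; 299 ± 51.3 against 3729 ± 929) and mir-210 (-3.57 ± 0.33). Other large falls were mir-196b (-3.56 ± 0.40), mir-28 (-3.44 ± 0.43) and let-7i (-3.39 ± 0.28). In total 220 hairpins fell and 0 rose with limma (224 had an unadjusted p under 0.05 in either direction; edgeR gave 224 falls and 0 rises, DESeq2 223 and 0). The median log2 fold change was -1.76, and 224 hairpins had libraries that did not overlap, against a chance share of 10%.

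By family, all 12 let-7 hairpins fell (median -1.78; 12 adjusted over the list alone; camera adjusted p = 0.0164, adjusted p = 0.0692 with the replicate number as a block in these 2 groups and 0.889 with an estimated correlation). All members also fell in miR-17-92 (12, median -2.32), miR-30 (6, -3.34), miR-181 (6, -2.77), miR-23/27/24 (6, -2.79), miR-15/16 (5, -1.83), miR-29 (4, -2.59) and mir-192, mir-194 and mir-215 (4, -2.75), with the same counts adjusted over each list alone and medians below 0 under each other scaling. A kept sign does not give the size: equal totals brought the median of all hairpins from -1.76 to -0.14. Calls of single members under that scaling are not given here. In miR-200 3 of 5 fell (-1.69), and all 3 of mir-183, mir-96 and mir-182 did (-1.49), a median that turned to 0.15 with equal totals. The miR-320 copies stood above other hairpins (adjusted p = 0.00212; adjusted p = 0.197 with an estimated correlation) with a median of -0.04, which turned to 1.39 with median centring, 0.37 centred on the DGCR8-independent list and 1.60 with equal totals. The values of mir-320a (-0.04 ± 0.09) and mir-877 (-0.06 ± 0.41) did not pass the test and turned positive with median centring (1.39 and 1.37) and equal totals (1.60 and 1.58). Among microRNAs of other cell types mir-143, a smooth muscle microRNA, fell (-1.13 ± 0.47, adjusted p = 0.042), a call not made when adjusted over the list alone. It was lost under the 3 other scalings, with no filter (0.168), a pseudocount of 10 (0.0539), only these 2 groups (0.0695) or no variance trend (0.0515). It was also lost in both count tests (0.0968 and 0.0831) and without WT replicate 1 or 2 or C352A replicate 2 or 3 (0.0549 to 0.211). Counts were 86 up and 122 down with median centring (median of all -0.33), 1 and 202 centred on the DGCR8-independent list (-1.35), and 97 and 99 with equal totals (-0.14).

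Against mock, C352A raised 2 hairpins and lowered 48, with a median log2 fold change of -0.66. The rises were mir-3615 (2.44 ± 0.47, adjusted p = 0.00501; 1291 against 283 scaled reads) and mir-1306. The falls included mir-4521 (-3.28 ± 0.48), mir-423 (-1.48 ± 0.21; 1471 ± 140 against 4115 ± 535), let-7d (-1.47 ± 0.25) and mir-877 (-1.45 ± 0.41, adjusted p = 0.0261). Of hairpins that rose with WT, let-7i had 0.45 ± 0.28, mir-30a 0.15 ± 0.34 and mir-92a-1 -0.41 ± 0.35, none past the threshold, and 3 of 12 let-7 hairpins fell (5 adjusted over the list alone; list median -0.39, 0.33 with median centring). The falls of mir-423 and let-7d were not called when libraries were centred on the median hairpin (adjusted p = 0.0697 and 0.0704) or on the DGCR8-independent list (0.13 and 0.194). That of mir-877 was lost under the 3 other scalings (0.0705 to 0.413), with no filter (0.118) and without mock library b or c or C352A replicate 1 (0.0649 to 0.109). The count of 50 became 16 with median centring (13 up and 3 down), 7 centred on the DGCR8-independent list (4 and 3) and 49 with equal totals (7 and 42). It was 31, 24 and 23 without mock library a, b or c, and 23 and 28 without C352A replicate 1 or 3.

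The P351A form lowered many of the same families relative to WT, but not let-7 as a whole, in a comparison between 2 sets of libraries that mir-373 also sets apart. Beside mir-373, the falls included mir-30a (-4.00 ± 0.34, adjusted p = 4.99e-08; 228 ± 18.4 against 3729 ± 929 scaled reads), mir-193b (-3.59 ± 0.47), mir-10a (-3.42 ± 0.24), mir-29b-2 (-3.26 ± 0.47), mir-27a (-3.24 ± 0.28), mir-196b (-3.23 ± 0.40) and mir-26a-1 (-3.16 ± 0.27). The rises included mir-9-1 and its copies, neural microRNAs (2.16 ± 0.47, adjusted p = 0.000962; 859 against 229; 2.77 without WT replicate 1), and mir-532 (1.74 ± 0.36). The named rises of mir-455 (1.09 ± 0.38) and mir-101-1 (0.82 ± 0.31) were each lost without WT replicate 2 or 3 or P351A replicate 2 or 3 (adjusted p 0.0518 to 0.133) and with no filter (0.0763 and 0.074). With only these 2 groups in the fit mir-101-1 was lost too (0.0672). In total 172 hairpins fell and 11 rose (median -0.95; 27 rose without WT replicate 1, and 4 without WT replicate 2 or 3 or P351A replicate 2 or 3), and 218 did not overlap, against a chance share of 10%.

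All 6 miR-23/27/24 hairpins fell in P351A relative to WT (median -2.92; 6 adjusted over the list alone; camera adjusted p = 0.00758, adjusted p = 0.889 with an estimated correlation). All 6 miR-30 (-2.23), all 6 miR-181 (-1.83), all 4 mir-192, mir-194 and mir-215 (-1.64), all 3 mir-183, mir-96 and mir-182 (-2.45) and 4 of 5 miR-15/16 hairpins (-2.31) fell too, with medians below 0 under each scaling. In the let-7 family 2 of 12 fell, let-7i among them (-2.56 ± 0.28), while let-7a-1 gave 0.32 ± 0.22 (a rise of 0.58 without WT replicate 1, and of 1.07 to 1.32 under the 3 other scalings), and the list median was 0.14. Of 12 miR-17-92 hairpins 1 fell (median -0.50) and of 5 miR-200 hairpins 2 fell (-0.63), but both medians turned positive under every other scaling, to between 0.11 and 0.50. The mirtrons mir-877 (-1.49 ± 0.41) and mir-1226 (-1.20 ± 0.31) fell, neither past the threshold under the 3 other scalings (adjusted p 0.204 to 0.344 and 0.202 to 0.577), while mir-320a (0.19 ± 0.09) did not pass the test on the authors' scale but rose under the 3 others (0.94 to 1.19). Of 5 tested microRNAs of other cell types 4 rose (median 2.16; camera adjusted p = 0.00021, adjusted p = 0.678 with an estimated correlation): the 3 mir-9 copies and mir-143 (1.37 ± 0.47). The last was lost with no filter (0.101) and without WT replicate 2 or 3 or P351A replicate 2 or 3 (0.0581 to 0.0942). Counts were 68 up and 74 down with median centring (median of all 0.05), 49 and 69 centred on the DGCR8-independent list (-0.01), and 48 and 91 with equal totals (-0.21).

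The embryonic stem cell microRNA mir-373 (chromosome 19, 53788705 to 53788773, plus strand) split the libraries by group. It held 1038 to 5176 scaled reads in each of the 9 mock, WT and C352A libraries and 0 reads in each of the 6 libraries of P351A and P351A plus ALA. The parental and dCTT libraries have no value for mir-373, and the hairpins listed for them reach at least 50.7 in the higher library. Its absence from the 6 libraries is therefore not shown to be a loss from the source cells. Against a floor of 3 reads over the group, mir-373 was at least 8126-fold higher in mock than in P351A and at least 3765-fold higher than in P351A plus ALA; for WT the bounds were 7158-fold and 3317-fold and for C352A 2839-fold and 1315-fold. Its neighbour mir-372 and mir-202 were likewise read in mock, WT and C352A, with 0 reads in P351A and 2 and 1 in P351A plus ALA. No group lies on both sides of this split, so a comparison of P351A or P351A plus ALA with mock, WT or C352A cannot be told apart from a difference between 2 batches of libraries. Without mir-371 to mir-373 and mir-202 the count for P351A against WT was 180 in place of 183. All 6 libraries of P351A and P351A plus ALA lay above or below all 9 others for 14 of 336 hairpins, against 78 when WT and P351A plus ALA and 60 when mock and C352A were set against the rest. C352A and P351A against the rest also gave 14, and every other pair of groups gave between 0 and 7.

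Across that split, P351A raised 76 hairpins over mock and lowered 87 (median -0.03). The rises included mir-107 (2.89 ± 0.27, adjusted p = 3.82e-07, with 17082 ± 2033 against 2313 ± 450 scaled reads) and mir-103a-1 (2.88 ± 0.27). Here and below these 2 hold nearly the same reads and are 1 signal. Others were mir-19a (3.07 ± 0.53), mir-3615 (2.96 ± 0.47) and mir-125b-2 (6.43 ± 1.34, from 13.5 ± 21.3 in mock, with 7.89 without mock library a and 5.25 without b). Of the let-7 family 11 of 12 hairpins rose (median 1.59; 11 adjusted over the list alone; camera adjusted p = 0.000177, adjusted p = 0.889 with an estimated correlation). So did 9 of 12 miR-17-92 hairpins (1.42; adjusted p = 0.00758, adjusted p = 0.889 with an estimated correlation). All 3 of mir-183, mir-96 and mir-182 fell (-1.19), as did mir-16-2 (-1.27 ± 0.24; adjusted p = 0.37 centred on the DGCR8-independent list), mir-877 (-2.88 ± 0.41) and mir-4521 (-3.62 ± 0.48), while mir-30a (-0.23 ± 0.34) and mir-222 (-0.06 ± 0.17) did not pass the test. The same 4 microRNAs of other cell types, mir-9-1 to mir-9-3 and mir-143, were higher than in mock (list median 2.27). The control hairpin mir-320a rose (0.33 ± 0.09, adjusted p = 0.0081), a call lost with DESeq2 (0.148) and without the variance trend (0.186), and a value that turned to -0.37 with equal totals. Counts were 114 up and 73 down with median centring (0.26), 153 and 25 centred on the DGCR8-independent list (0.87), and 55 and 164 with equal totals (-0.72).

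Set directly against C352A, also across the split, P351A had 124 hairpins that rose and 47 that fell (median 0.56; 23 to 28 fell without replicate 2 or 3 of either group). The rises included mir-125b-2 (5.67 ± 1.34; 6.51 without C352A replicate 1 and 4.74 without C352A replicate 3), mir-532 (3.60 ± 0.36), mir-19a (3.60 ± 0.53), mir-107 (3.55 ± 0.27) and mir-103a-1 (3.53 ± 0.27). All 12 let-7 hairpins rose (median 2.11; 12 adjusted over the list alone; adjusted p = 0.000241, adjusted p = 0.889 with an estimated correlation). So did 10 of 12 of miR-17-92 (2.16; adjusted p = 0.0231, adjusted p = 0.889 with an estimated correlation) and 4 of 5 microRNAs of other cell types (2.85). Falls included mir-16-1 (-1.53 ± 0.24), mir-126, an endothelial microRNA (-1.55 ± 0.26), mir-7641-2 (-1.66 ± 0.29) and mir-877 (-1.43 ± 0.41; adjusted p = 0.0548 without C352A replicate 2 and 0.0616 with no filter). For mir-30a (-0.38 ± 0.34) and mir-27a (-0.09 ± 0.28) no difference passed the test. Counts were 86 up and 78 down with median centring (0.12), 176 and 17 centred on the DGCR8-independent list (1.09), and 65 and 105 with equal totals (-0.29).

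ALA treatment of the P351A cells raised hairpins such as mir-30a and mir-193b, which were lower in P351A than in WT. This comparison lies within the libraries that lack mir-373. Large rises included mir-149 (3.97 ± 0.71; 5.10 without ALA replicate 3 and 3.36 without ALA replicate 1), mir-877 (3.43 ± 0.41, adjusted p = 5.34e-06; 5451 ± 2194 against 486 ± 135 scaled reads), mir-30a (3.39 ± 0.34, adjusted p = 9.81e-07; 2594 ± 1125 against 228 ± 18.4) and mir-193b (3.05 ± 0.47). Others were mir-30b (3.04 ± 0.51; 3.71 without ALA replicate 3), mir-4521 (2.82 ± 0.48; adjusted p = 0.053 centred on the DGCR8-independent list) and mir-22, in an exon of its host transcript MIR22HG (chromosome 17, 1713903 to 1713987, minus strand; 2.79 ± 0.24; 30341 ± 6643 against 4305 ± 149). The value of mir-222 rose by 2.39 ± 0.17 (adjusted p = 0.178 centred on the DGCR8-independent list), while its neighbour mir-221 gave 0.03 ± 0.30. In total 150 hairpins rose and 10 fell (median 0.81; 2 to 5 fell without any 1 library but ALA replicate 2, where 9 did), and 236 did not overlap, against a chance share of 10%. The named falls, mir-19a (-1.48 ± 0.53), mir-561 (-1.40 ± 0.45), mir-3615 (-1.39 ± 0.47) and mir-501 (-1.24 ± 0.41), were each lost with no filter (adjusted p 0.0898 to 0.158) and when 1 of several libraries was left out (0.0545 to 0.117). These libraries were for mir-19a P351A replicate 2 or 3 or ALA replicate 1 or 3, for mir-561 P351A replicate 2 or ALA replicate 1, for mir-3615 P351A replicate 1 or 2 or ALA replicate 2 or 3, and for mir-501 P351A replicate 1 or 2 or ALA replicate 3.

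Families moved unevenly with ALA. All 6 miR-30 hairpins (median 1.94) and all 3 of mir-183, mir-96 and mir-182 (2.15) rose, medians that stayed above 0 under each scaling. That gives their sign and not their size. Centring on the DGCR8-independent list lowered the median of all hairpins from 0.81 to -1.05, with 17 up and 166 down. All 6 miR-23/27/24 (1.46) and 5 of 6 miR-181 hairpins (1.40) rose, but centred on the DGCR8-independent list these medians were -0.41 and -0.46. Of the let-7 hairpins 8 of 12 rose (0.75; 10 adjusted over the list alone), a median that turned to -0.39, -1.11 and -0.03 under the 3 other scalings, and of 12 miR-17-92 hairpins 1 fell (median 0.46, between -0.32 and -1.41 under the other scalings). The miR-320 copies stood below other hairpins (median -0.20, 3 of 7 fell; camera adjusted p = 0.00235, adjusted p = 0.197 with an estimated correlation). So did the microRNAs of other cell types (median -1.0; adjusted p = 0.00644, adjusted p = 0.889 with an estimated correlation).

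All 5 tested members of the DGCR8-independent list rose with ALA (median 1.78; 5 adjusted over the list alone; camera adjusted p = 0.165, adjusted p = 0.889 with an estimated correlation), a median that was -0.089 when libraries were centred on the list itself. Beside mir-877 these included mir-1226 (1.57 ± 0.31, adjusted p = 0.00052), lost with median centring (0.43, adjusted p = 0.183) and centred on the list (-0.29, 0.451). The rise of mir-484 (1.78 ± 0.54, adjusted p = 0.0135; 2.51 without ALA replicate 3) was lost without ALA replicate 1 or 2 (0.0849 and 0.0543), with no filter (0.0925) and under the 3 other scalings, with a value of -0.089 centred on the list. The rise of mir-320a was small (0.29 ± 0.09, adjusted p = 0.019), was not called without P351A replicate 3 or ALA replicate 2 (0.0658 and 0.071), with no filter (0.0537), without the variance trend (0.255) or by DESeq2 (0.203), and its value turned to -0.85, -1.58 and -0.50 under the other scalings. Counts for the comparison were 45 up and 105 down with median centring (median of all -0.33), 17 and 166 centred on the DGCR8-independent list (-1.05), and 74 and 61 with equal totals (0.06).

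P351A plus ALA still differed from WT, across the split by mir-373: 46 hairpins rose and 68 fell (median -0.22). The rises included mir-877 (1.93 ± 0.41), mir-532 (1.64 ± 0.36), mir-107 (1.64 ± 0.27) and mir-103a-1 (1.63 ± 0.27). The falls included mir-196b (-2.34 ± 0.40), mir-16-1 (-2.33 ± 0.24; 3495 ± 1076 against 17175 ± 2515 scaled reads), mir-27a (-1.78 ± 0.28) and mir-561 (-2.01 ± 0.45; -1.38 without ALA replicate 1). For mir-30a (-0.61 ± 0.34) and mir-34a (0.71 ± 0.46; 1.27 and past the threshold without WT replicate 1) no difference passed the test. Of 12 let-7 hairpins 7 rose and let-7i fell (list median 0.87, -0.05 centred on the DGCR8-independent list; 8 adjusted over the list alone; camera adjusted p = 0.0164, adjusted p = 0.889 with an estimated correlation). The fall of let-7i (-0.78 ± 0.28, adjusted p = 0.0438) was lost without WT replicate 1 or ALA replicate 1 or 2 (0.0635 to 0.217). It was also lost with a pseudocount of 0.1, no filter, only these 2 groups, no variance trend or DESeq2 (0.0506 to 0.191). Without WT replicate 1 the split turned to 58 up and 37 down (median 0.0097) and without ALA replicate 3 to 51 and 45. It was 33 and 72 without WT replicate 2, 25 and 65 without WT replicate 3, 24 and 32 without ALA replicate 1 and 29 and 47 without ALA replicate 2. With only these 2 groups in the fit it was 18 and 31. Counts were 48 up and 103 down with median centring (-0.36), 1 and 170 centred on the DGCR8-independent list (-1.14), where the named rises of mir-107, mir-103a-1 and mir-532 were lost (adjusted p 0.136 to 0.154), and 49 and 88 with equal totals (-0.25).

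Over mock, P351A plus ALA raised 166 hairpins and lowered 30 (median 0.87), again across the split. The rises included mir-149 (4.27 ± 0.71; 5.41 without ALA replicate 3 and 3.66 without ALA replicate 1), mir-107 (3.71 ± 0.27, adjusted p = 9.19e-09; 30290 ± 5100 against 2313 ± 450 scaled reads), mir-103a-1 (3.70 ± 0.27) and mir-34a (3.47 ± 0.46). Further rises were mir-30a (3.16 ± 0.34) and let-7i (3.05 ± 0.28). All 12 let-7 hairpins rose (median 2.53; 12 adjusted over the list alone; adjusted p = 0.000241, adjusted p = 0.889 with an estimated correlation), and all 6 of miR-30 (2.76). The miR-320 copies were lower than other hairpins (median -1.09, 5 of 7 fell and 2 rose; adjusted p = 0.00758, adjusted p = 0.272 with an estimated correlation), among them mir-320c-2 (-1.45 ± 0.26). Of the microRNAs of other cell types 4 of 5 rose (1.26, -0.21 with equal totals), and mir-320a rose (0.62 ± 0.09), a value that turned to -0.23, -0.35 and -0.86 under the other scalings. Counts were 85 up and 95 down with median centring (0.03), 59 and 79 centred on the DGCR8-independent list (-0.10), and 51 and 144 with equal totals (-0.55). Of the 117 tests of lists over all comparisons, 15 passed the threshold with the preset correlation and 0 with an estimated correlation.

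The hairpin mir-1306, which lies in a coding exon of DGCR8 (chromosome 22, 20086058 to 20086142, plus strand), was read in every group given a DGCR8 form and held 1 read over the 3 mock libraries. Its ratio to mock was 67.3 in WT (95% counting interval 11.7 to 2693), 37.5 in C352A (6.52 to 1499), 24.5 in P351A (4.29 to 978) and 292 in P351A plus ALA (52.2 to 11550). Between groups with reads, mir-1306 rose in P351A plus ALA over P351A (3.40 ± 0.50, adjusted p = 4.1e-05) and over WT (2.01 ± 0.50), the latter not past the threshold centred on the DGCR8-independent list (adjusted p = 0.125) or with a pseudocount of 0.1 (0.103). The falls of mir-1306 from WT to C352A (-1.32 ± 0.50, adjusted p = 0.027) and to P351A (-1.40 ± 0.50) each lost the threshold when WT replicate 1 or 2 or replicate 2 or 3 of the mutant was left out. The values were then -1.29 to -0.97 in C352A (adjusted p 0.0614 to 0.132) and -1.37 to -1.31 in P351A (0.0542 to 0.0729). Both also lost it with no filter (0.11 and 0.107), with a pseudocount of 0.1 (0.223 and 0.218) and under the 3 other scalings, where the former turned to 0.11 with median centring and 0.25 with equal totals. The other hairpin in a DGCR8 exon, mir-3618 (20085746 to 20085833), held 8 reads over the 4 DGCR8 groups and 2 in mock.

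Hairpins with UGU in the apical loop, a motif that DGCR8 is known to favour, were compared with the rest. The UGU class includes let-7i and mir-10a; mir-30a and mir-21, whose UGU lies outside the loop as extended by 2 nt, fall in the other class. The mean log2 fold change of the UGU class exceeded that of other hairpins by 0.40 for WT over mock and by 0.39 for P351A plus ALA over P351A, and lay below it for C352A over WT (difference -0.39) and P351A over WT (-0.60). None of these 4 differences passed the test after adjustment over 9 comparisons (camera adjusted p 0.342 to 0.431; adjusted p = 0.934 with an estimated correlation), and the smallest unadjusted p was 0.0401. Within libraries, the median log2 level of UGU hairpins exceeded that of the others by 0.66 ± 0.25 in mock, 0.84 ± 0.23 in WT, 0.27 ± 0.13 in C352A, 0.14 ± 0.07 in P351A and 0.84 ± 0.27 in P351A plus ALA (SD, n = 3). The 3 libraries of C352A and of P351A lay below those of WT and of mock, and those of P351A plus ALA above those of P351A, each at the smallest p (0.1) that an exact 2-sided permutation test of 3 against 3 can give (0.18 after adjustment). By mean log2 fold change the UGU class and the others differed by 0.010 for C352A over mock and -0.20 for P351A over mock (adjusted p = 0.693 and 0.794). The loop was also extended by 6 nt on each side, a choice made after seeing the data that moves mir-30a and mir-21 into the UGU class. Camera was run on that class with the preset correlation only, not with an estimated one. The differences were then 0.66 for WT over mock and -0.66 for C352A over WT (adjusted p = 0.00752 for both). They were -0.41 for P351A over WT and 0.28 for P351A plus ALA over P351A (adjusted p = 0.273 for both). Among hairpins at least 4-fold lower in dCTT than in parental cells these 4 differences were 0.35, -0.28, -0.36 and 0.50 (adjusted p = 0.198, 0.402, 0.402 and 0.076).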

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

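Count tests on recovered reads, 1 hairpin per name, counts without mir-371 to mir-373 and mir-202, other UGU classes and a replicate block over C352A and WT alone were added after seeing the data. For counts of calls, the same means here a total of similar size, whatever its split into rises and falls. WT against mock with equal totals thus counts as the same, with 54 rises and 126 falls in place of 187 and 25. So does P351A plus ALA against P351A centred on the DGCR8-independent list, with 17 and 166 in place of 150 and 10. Of alternatives fixed in advance for a comparison, 224 results stayed the same and 27 moved. Of added ones 72 stayed, 1 moved and 2 became stronger. Of those fixed in advance for the largest rises and falls, the hairpins named throughout, lists and single values, 2145 stayed the same, 122 became weaker, 9 stronger, 21 moved and 20 reversed. Of added ones 587 stayed, 5 became weaker and 2 stronger. Hairpins named only as members of a list, such as mir-222 and mir-143, are not in these counts, so their lost calls come on top.

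With a mean of 100 or more fewer hairpins are tested, and the counts were 135 for WT against mock, 32 for C352A, 96 for P351A and 119 for P351A plus ALA against mock. They were 128 for C352A and 91 for P351A against WT, 70 for P351A plus ALA against P351A and 106 for P351A against C352A. The C352A against mock count (50) became 20 with no filter, a change whose cause was not tested. It became 16 with median centring and 7 centred on the DGCR8-independent list. These centrings shift all hairpins of a library alike: the median log2 fold change went from -0.66 to 0.07 and -0.30, and the 48 falls became 3 and 3. P351A against WT gave 118 centred on the DGCR8-independent list, where its median went from -0.95 to -0.01. P351A plus ALA against WT gave 49 with only these 2 groups, for reasons that were not tested. Leaving out 1 library gave 181 to 228 for WT against mock, 23 to 41 for C352A against mock (23 without mock c or C352A replicate 1) and 56 to 105 for P351A plus ALA against WT (56 without ALA replicate 1). It gave 121 to 151 for P351A plus ALA against P351A and 205 to 224 for C352A against WT. The 15 list tests past the threshold became 49 with no filter, 25 with equal totals, 0 with an estimated correlation and 8 with 1 hairpin per name. The UGU difference with the loop extended by 6 nt was 0.66 for WT against mock, 0.53 for P351A plus ALA against mock and -0.66 for C352A against WT. The parental over dCTT median was 5.67 with a pseudocount of 0.1, 4.52 with 10, 5.66 with a mean of 100 and 1.13 with median centring, which removes a shared loss by construction. The restored against lost correlation was 0.453 with a pseudocount of 10.

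Reversals came with rescaling, which shifts all hairpins of a library alike. For mir-320a the values were -0.58 (median centring) and -1.31 (equal totals) in WT against mock, -0.37 (equal totals) in P351A against mock, -0.23, -0.35 and -0.86 (median, DGCR8-independent list, equal totals) in P351A plus ALA against mock. They were 1.39 and 1.60 (median, equal totals) in C352A against WT, -0.85, -1.58 and -0.50 in P351A plus ALA against P351A, -0.44 (DGCR8-independent list) in P351A plus ALA against WT, and -0.20 and -0.66 (median, equal totals) in P351A against C352A. With equal totals mir-484 was -0.072 in WT against mock, and centred on the DGCR8-independent list -0.089 in P351A plus ALA against P351A. In C352A against WT, median centring and equal totals gave mir-877 1.37 and 1.58 and mir-1306 0.11 and 0.25.

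In C352A against WT, where every same-number pair correlated over 0.1, the replicate block gave 221 calls, and 217 with only these 2 groups, in place of 220. It changed no other call of a named hairpin or list there than that of let-7. Elsewhere not every same-number pair correlated over 0.1 and the libraries share only a number. There the block gave 181 calls for P351A against WT, 158 for P351A plus ALA against P351A, 115 for P351A plus ALA against WT and 175 for P351A against C352A. Own-number correlations were highest for 0, 2, 3 and 0 of 6 libraries. With the block the adjusted p was 0.06 for mir-101-1 in P351A against WT, 0.0655 for let-7i in P351A plus ALA against WT and 0.0515 for mir-320a in P351A against C352A. No paired analysis was possible in the 4 with mock because its columns could not be matched to replicate numbers. The planned DESeq2 and TMM settings for raw counts were not run as planned, since most columns are scaled. Removing the filter for the pair of single libraries and median centring for the correlation change nothing and show nothing. With read counts that sum to 146023 in the shallowest mock library, low hairpins are limited by counting error.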

Other observations

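Values of the fixed comparisons and lists given here were planned. The tests of explanations were chosen after the result was seen, except those of the mir-302 and mir-367 cluster and of mir-3618. The p53 targets mir-34a and mir-34c and the growth-promoting pair mir-221 and mir-222 are too few to test as lists. In C352A relative to WT all 4 fell: mir-34a (log2 fold change -3.83 ± 0.46), mir-34c (-4.33 ± 0.68), mir-221 (-2.96 ± 0.30) and mir-222 (-1.33 ± 0.17; n = 3 each). The fall of mir-222 was lost with median centring and equal totals (adjusted p = 0.758 and 0.249). With ALA over P351A, mir-34a (1.49 ± 0.46) and mir-34c (2.51 ± 0.68) rose, calls lost under the 3 other scalings and with no filter (adjusted p 0.0566 to 0.52), and for mir-34c also with a pseudocount of 0.1 (0.119). That of mir-34a was also lost without P351A replicate 1 or ALA replicate 2 (0.0541 and 0.07). The neighbours mir-221 and mir-222 parted in P351A over mock, across the split by mir-373: mir-221 rose (1.44 ± 0.30) while mir-222 gave -0.06 ± 0.17.

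In the parental and dCTT libraries the remaining lists had these median log2 ratios, with the percentile among 10000 random lists: miR-15/16 4.43 (6 hairpins, 4.88), miR-17-92 5.47 (12, 8.84) and miR-29 4.70 (4, 15.1). The others were miR-30 5.61 (6, 19.4), the mir-183, mir-96 and mir-182 cluster 4.62 (3, 6.42), mir-192, mir-194 and mir-215 5.51 (4, 77.2) and hairpins with an apical UGU 5.36 (64, 3.53).

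The hairpins mir-373, mir-372 and mir-202 were read in the 9 libraries of mock, WT and C352A and not, or with 1 or 2 reads, in the 6 of P351A and P351A plus ALA. RNA from embryonic cells is argued against by the summed mir-302 and mir-367 value, which was 0.0949% of mir-373 over the 9 libraries (19 reads in 6 hairpins). Release by DGCR8 activity is argued against by the WT over mock value of mir-373, -0.14 ± 0.42, whose upper limit at 2 SE (0.70) lies under the median hairpin (1.13). A batch of libraries or of cells cannot be told apart from the DGCR8 form and treatment, since 0 groups have libraries on both sides. No other biological explanation was tested.

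All 5 tested members of the DGCR8-independent list rose in P351A plus ALA over P351A. A scale factor moves all hairpins of a library alike, and the median of the other 4 members exceeded mir-320a by 1.73. The members thus moved unequally, which a factor alone does not give. Whether scale factors made all 5 rise cannot be decided from this gap, since the authors' scale itself holds mir-320a close to level. The value of mir-320a was -0.85 with median centring, -1.58 centred on the list and -0.50 with equal totals. The rise of all 5 therefore depends on the scale. Whether ALA, which the labels do not spell out, acts on these hairpins or on their host transcripts stays open and was not tested.

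The hairpin mir-1306 was read in each group given a DGCR8 form and held 1 read in mock. Restored Microprocessor activity alone is argued against: in C352A over mock the lower 95% limit of its log2 ratio, 2.70, lies above the central 95% of other hairpins (upper limit 0.56). A candidate explanation is reads from an introduced DGCR8 coding sequence, in which mir-1306 lies. By contrast mir-3618, in an exon upstream of the coding sequence, had a pooled ratio to mock of 0.45 (95% interval 0.0897 to 4.35; 8 and 2 reads), against 87.7 (15.7 to 3467) for mir-1306. The parental and dCTT libraries have no value for mir-1306, so whether it was lost there cannot be read. A rise over mock was also seen for mir-3615, which is not listed among the hairpins within DGCR8 and was not lower in dCTT cells. Its log2 ratio of parental over dCTT was -0.20 and its value in WT over mock 2.18, and it rose in C352A and P351A over mock. Why mir-3615 rose was not tested. With ALA over P351A, within the same DGCR8 form, mir-1306 rose too (3.40 ± 0.50). The amount of introduced sequence was not measured, so a difference in it between these groups stays open.

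For each of the 9 comparisons the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of the 10, the real split, gave as many calls. The real counts and the highest of the other splits were 212 and 0 for WT against mock, 50 and 0 for C352A against mock, 163 and 0 for P351A against mock, 196 and 0 for P351A plus ALA against mock. They were 220 and 1 for C352A against WT (0 in the 3 other splits that part all same-number pairs, as the real one does; the 6 others part only 1 pair), 183 and 0 for P351A against WT, 160 and 0 for P351A plus ALA against P351A, 114 and 16 for P351A plus ALA against WT and 171 and 0 for P351A against C352A.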
